A study of Mus musculus with 11 samples.

How the data were processed

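RNA sequencing was done on 11 libraries of mouse T cells from lymphoid tissue, in 5 groups taken from the sample labels. The groups were CD8 induced regulatory T cells (iTregs) without laminin (3 libraries), CD8 iTregs labelled as induced with laminin α5 (3), CD8 iTregs labelled as induced with laminin α5 plus an antibody against interferon-γ (3), CD4 iTregs (1) and naive CD8 T cells (1). Per the labels' protocols, RNA was extracted with a micro-scale column kit and libraries were made with a directional (strand-marking) kit.

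The deposited files hold raw counts, 1 whole-number count of reads per gene and library, which the authors made from aligned reads. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq and DESeq2 were used and the genome build was GRCm39; the annotation release, the strand setting and other counting options are not given in the sources used here. The values were checked to be whole numbers of at least 0 that sum to a different total in each library. Reads that were assigned to no gene (no feature, ambiguous or not uniquely aligned) stand in separate lines of each file and were kept out of library sizes and tests. They made up 14.0% to 17.2% of the reads listed in the 9 replicated CD8 libraries, 14.7% in the CD4 library and 20.3% in the naive library.

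Every file lists 53700 Ensembl gene IDs. Gene names came from GENCODE M21, which is on another build (GRCm38), so it was used for names, gene type, GC content and length and no coordinates are given. It names 52093 of the IDs, and 24457 of the 24649 IDs with at least 1 count. Some genes share stretches of sequence with other genes, among them Gbp6, Gbp10, Rps3a1, Rps3a3 and Rpl29, which are named below. Others are members of the gene lists that are not named below (Npm1, Tagap, Pgam1, Odc1, Ccnb1, Phgdh, Tuba1a, Bnip3l, Idi1, mt-Co1 and mt-Atp6). How reads were divided among such copies cannot be checked in the counts, so their values are less certain.

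Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, low-count genes were removed with filterByExpr, and groups were compared with the quasi-likelihood F test (robust dispersion and robust fit), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 3 comparisons among replicated CD8 groups came from 1 fit to 9 libraries (13715 genes, 6 residual degrees of freedom, biological coefficient of variation 14.9%). Comparisons with the CD4 and the naive library came from 1 fit to all 11 libraries (15600 genes, 15.1%), in which each lone library was assumed to vary like the replicated groups. Errors of log2 fold changes are standard errors from these fits, and levels are CPM (counts divided by the library size in mega counts) with TMM factors over all 11 libraries, as mean ± SD over 3 libraries or as a single value. Because CPM means and fitted log2 fold changes come from different weights, their ratios can differ slightly.

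Before the data were examined, 32 gene lists were written (immune programmes, metabolism, stress responses, adhesion, markers of other cell types and signs of RNA quality). A list of erythroid and platelet genes had 2 tested members and was left out, since 3 were required, so 31 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and fry. For every list the members that passed the threshold were counted with p-values adjusted over all genes and adjusted over the list alone.

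Genes named in the text follow a rule written before the data were examined. It takes 15 fixed genes, given in every comparison except 1 that is not reported here, then in each comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM in 1 group, no overlap between groups and a gene symbol that is not a predicted gene, clone, pseudogene or antigen receptor segment, and up to 4 members of each list with the smallest p-values. Where all libraries of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only.

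The scripts were tested on simulated counts, in 5 simulated tables with known changes. For the comparison of laminin with no laminin (13550 genes), 37.6% of genes changed 1.5-fold, 79.4% of genes changed 2-fold and 94.2% of genes changed 4-fold were recovered, and 6.64% of all calls were false. For the comparison with the lone naive library (14779 genes) the shares recovered were 6.27%, 50.7% and 87.3%, and 6.08% of calls were false. Over the 5 tables of each design 335, 335 and 330 genes were changed 1.5-, 2- and 4-fold, drawn from genes above a minimum mean count. Far more genes were called in both real comparisons, so the shares recovered and false need not hold there. A list with a planted change was called in 5 of 5 tables in each design, and 0 of 150 unchanged lists were called in either. Genes were drawn independently of each other, so the tables cannot show how camera behaves for lists whose members vary together. The lone library was drawn with the pooled spread, so the assumption that it varies like the replicated groups was not tested.

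Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no low-count filter and a stricter one (at least 5 CPM in 3 libraries), a fit to only the libraries compared or to all 11, the replicate number as a block, leaving out each library in turn, and a minimum fold of 2. Chosen after the data were seen were fits without replicate 1 of the laminin plus anti-interferon-γ group and, for the naive comparison, a fit without genes that share sequence with other tested genes. For the relation between comparisons that share libraries, counts without any group effect were simulated 50 times. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All 11 libraries were used.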

Results

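Gene expression was measured by RNA sequencing in mouse T cells induced to become regulatory T cells (iTregs) in culture, and in naive CD8 T cells. Cells carried an eGFP reporter of Foxp3, the transcription factor that defines regulatory T cells, and Foxp3-positive iTregs were sorted on day 3. Foxp3 levels of iTregs are thus levels within sorted cells and do not show how many cells became Foxp3-positive. Differences in Cd8a and Cd4 between CD8 and CD4 iTregs follow from the choice of cells. Cultures held 10 ng/ml of the growth cytokine IL-2 and 15 ng/ml of TGFβ on plates coated with antibodies against CD3 (4 µg/ml) and CD28 (1 µg/ml), which stimulate the T cell receptor and its co-receptor. Some CD8 cultures were also labelled as exposed to a coat of laminin α5 (1 µg/ml), a chain of the basement membrane protein laminin, without or with an antibody against interferon-γ. There were 3 libraries each of CD8 iTregs without laminin, CD8 iTregs labelled laminin and CD8 iTregs labelled laminin plus anti-interferon-γ, and 1 library each of CD4 iTregs and of naive CD8 T cells (low CD44, positive for CD62L).

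Reads assigned to genes (M, mega counts) numbered 16.8, 23.6 and 20.7 M in the 3 libraries without laminin and 16.2, 15.7 and 15.5 M in those labelled laminin. They numbered 18.6, 20.8 and 21.2 M in those labelled laminin plus anti-interferon-γ, 17.95 M in the CD4 library and 17.9 M in the naive library. Between 17450 and 19314 genes had at least 1 count. Cd8a (ENSMUSG00000053977), which encodes a chain of the CD8 co-receptor, was at 1527 ± 27.8 CPM (SD, n = 3) in the CD8 iTregs without laminin, 1187 CPM in the naive library and 20.4 CPM in the CD4 library. Mitochondrial transcripts took 0.661% ± 0.113 (SD, n = 3) of gene counts without laminin and 1.11% ± 0.234 in the group labelled laminin. The share was 0.780% ± 0.142 in the group labelled laminin plus anti-interferon-γ, 0.400% in the CD4 library and 1.18% in the naive library. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. The CD4 and naive groups have no replicate.

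In the names of the deposited tables the 2 laminin groups are exchanged relative to the sample labels. Groups here follow the labels and are called by them throughout. Under the table names, the comparison of each laminin group with the group without laminin would exchange places with the other, and every change between the 2 laminin groups would take the opposite sign.

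The 3 groups of CD8 iTregs separated in a principal component analysis of log2 CPM. The first component held 54.1% of the variance and set the libraries without laminin (scores -43.2, -46.2 and -53.4) apart from all 6 others, which scored between 1.85 and 57.0. Replicate 1 of the group labelled laminin plus anti-interferon-γ scored 57.0, away from 11.4 and 10.5 of replicates 2 and 3. Replicate 1 of the group labelled laminin scored 1.85, away from 30.7 and 31.4 of its replicates 2 and 3. The second component, with 17.1%, parted the 2 laminin groups.

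**Figure D1:**
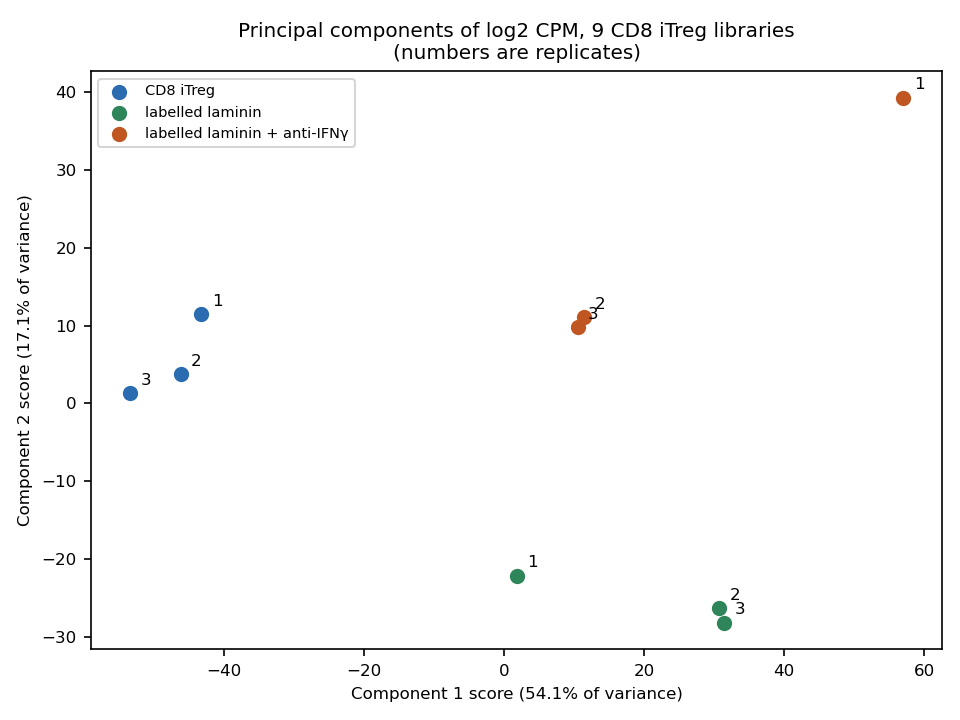
Scores of the 9 CD8 iTreg libraries on principal components 1 (x axis, 54.1% of variance) and 2 (y axis, 17.1%) of log2 CPM, 1 point per library, coloured by labelled group and numbered by replicate. The libraries without laminin lie at the left (-43.2 to -53.4 on component 1), and replicate 1 of the group labelled laminin plus anti-interferon-γ lies apart at 57.0. Replicate 1 of the group labelled laminin lies at 1.85, apart from its replicates 2 and 3.

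The first comparison asked how CD8 iTregs labelled as induced on laminin α5 differed from those induced without it. In the libraries labelled laminin, Foxp3 (ENSMUSG00000039521) rose modestly, and Ifng and 32 of 37 interferon-γ response genes fell. Foxp3 was at 433 ± 24.7 CPM against 294 ± 20.8 (SD, n = 3 each), a log2 fold change of 0.56 ± 0.11 (SE; edgeR adjusted p = 0.00492). Ifng (ENSMUSG00000055170), which encodes interferon-γ, was at 2.55 ± 0.811 against 44.4 ± 9.02 CPM, a log2 fold change of -4.11 ± 0.27 (adjusted p = 2.08e-05). The hypoxia (17 of 22 members) and cholesterol (12 of 24) lists rose and the ribosome biogenesis list (33 of 40) fell. These 3 list calls were lost with an estimated correlation (adjusted p = 0.293, 0.461 and 0.461). In all, 4320 of 13715 genes changed (2227 higher and 2093 lower), of which 1063 changed at least 2-fold (762 higher and 301 lower).

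Among regulatory T cell genes, Lrrc32, which encodes the TGFβ-docking receptor GARP, rose with a log2 fold change of 0.86 ± 0.08 (270 against 149 CPM, edgeR adjusted p = 0.000155). Ctla4, the inhibitory receptor that competes for CD28 ligands, rose by 0.69 ± 0.16 (431 against 268 CPM, adjusted p = 0.00952), a call that was lost without library 2 of the laminin group (0.61), and Tnfrsf4 rose by 0.70 ± 0.12. Il2ra, the IL-2 receptor α chain (-0.31 ± 0.14, adjusted p = 0.11), and Ikzf2, the transcription factor Helios (-0.43 ± 0.34, adjusted p = 0.351), did not pass the test. The regulatory T cell list as a whole was not called (12 of 31 members higher and 6 lower, the same counts adjusted over the list alone, adjusted p = 0.09). Cd8a (-0.11 ± 0.07, adjusted p = 0.284), Cd4 (0.21 ± 1.07, adjusted p = 0.895) and Tgfb1 (0.27 ± 0.13, adjusted p = 0.127) did not pass either, nor did the laminin receptor genes Itga6 (0.17 ± 0.13, adjusted p = 0.338), Itgb1 (-0.19 ± 0.13, adjusted p = 0.273) and Dag1 (-0.09 ± 0.12, adjusted p = 0.564). Without library 1 of the laminin group, Tgfb1 (0.37) and Itgb1 (-0.36) passed.

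The fall reached most measured genes of the interferon response. The transcription factor gene Irf1 changed by -1.79 ± 0.11 (82.1 against 286 CPM, edgeR adjusted p = 1.85e-05), and Iigp1, which encodes an interferon-induced GTPase, by -4.46 ± 0.42 (13.5 against 298 CPM). Ubd (ENSMUSG00000035186) had 0 counts in the libraries labelled laminin against 5.27 CPM, at least 83.6-fold lower. The steepest falls also included the chemokine Ccl1 (-5.12 ± 0.36), Gbp10 (-4.87 ± 0.62), the antiviral GTPase Mx1 (-4.40 ± 0.57), the gene model AC151990.1 (-4.33 ± 0.51) and Usp18 (-4.12 ± 0.50). Of 37 interferon-γ response genes 32 fell and 1 rose (33 and 1 adjusted over the list alone; camera adjusted p = 2.69e-37). Of 31 type I interferon response genes 27 fell and 0 rose (28 and 0 adjusted over the list alone; adjusted p = 1.45e-26). The interferon-γ (adjusted p = 0.0618) and type I (adjusted p = 0.131) lists lost their calls with an estimated correlation.

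**Figure D2:**
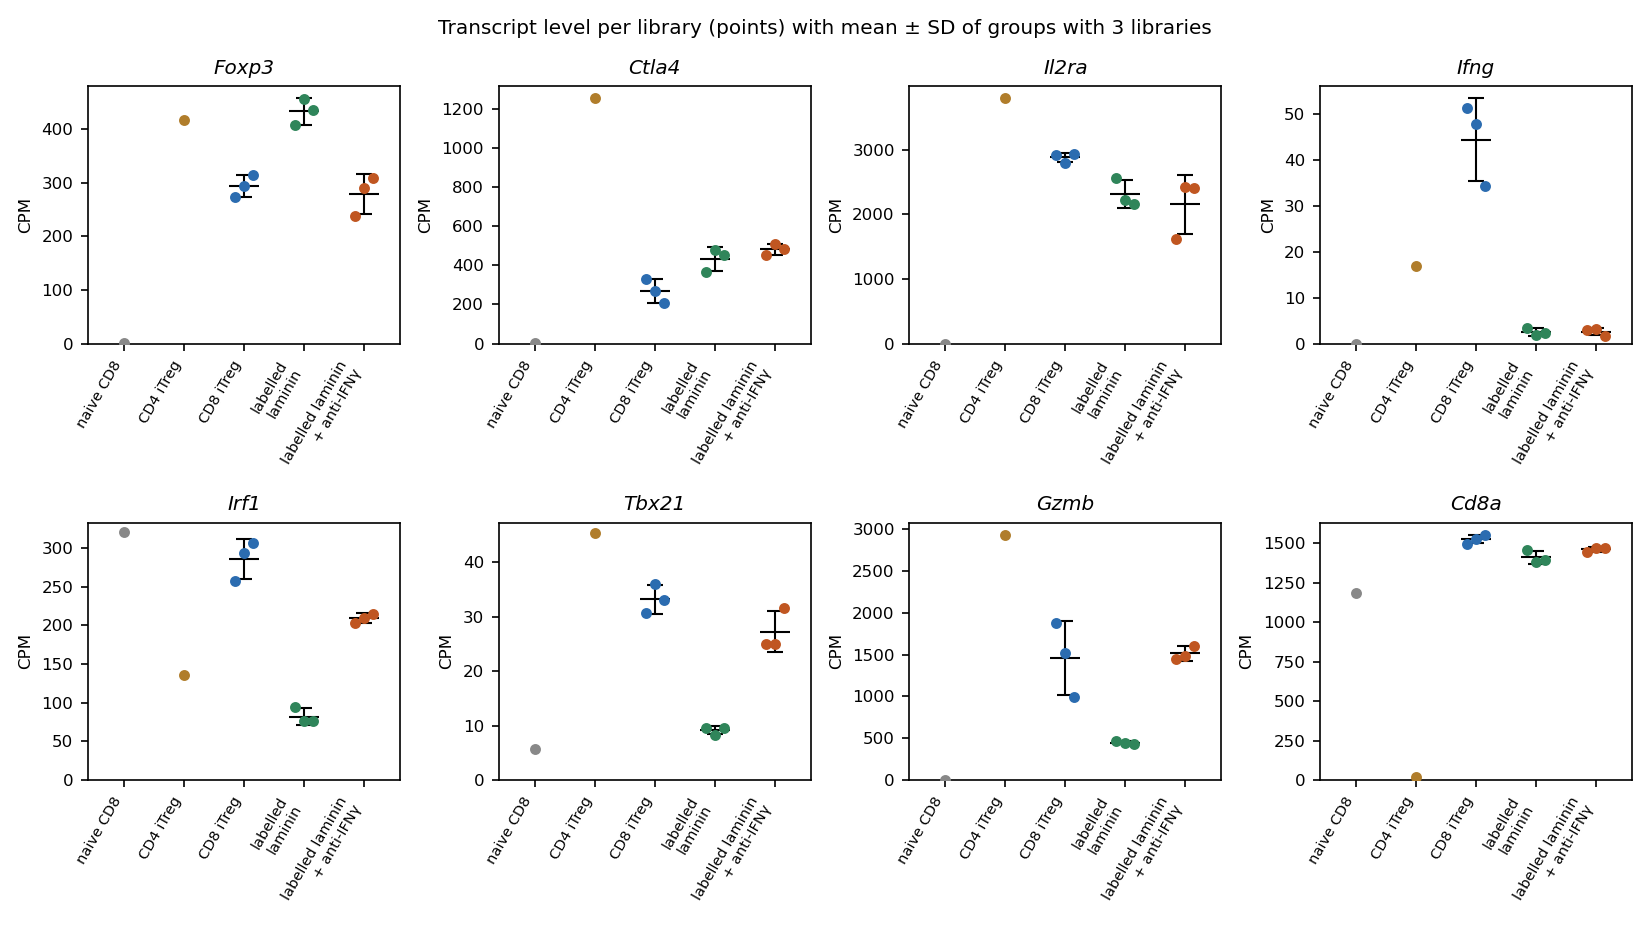
Transcript levels in CPM (y axes) of 8 fixed genes in every library (points) of the 5 groups on the x axis, with mean ± SD for groups of 3 libraries. Ifng lies at 2.55 and 2.61 CPM in both laminin groups against 44.4 CPM without laminin, while Irf1, Tbx21 and Gzmb are lower in the group labelled laminin alone than in the other CD8 iTreg groups.

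Effector genes fell alongside. Gzmb, a granule protease of killer cells, went from 1464 ± 442 to 447 ± 21.1 CPM (log2 fold change -1.71 ± 0.18, edgeR adjusted p = 0.00031). Gzma changed by -3.74 ± 0.24 and Tbx21, which encodes the type 1 regulator T-bet, by -1.86 ± 0.13 (9.15 against 33.2 CPM, adjusted p = 2.25e-05). The related factor Eomes was at 37.1 against 198 CPM. Chemokine genes Xcl1 (-2.24 ± 0.15), Ccl3 (-3.93 ± 0.21) and Ccl4 (-2.64 ± 0.15) fell. Of 21 cytokine and chemokine genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.12e-17), the call that held with an estimated correlation (adjusted p = 0.00294). The cytotoxic list fell with 11 of 26 members lower and 4 higher (11 and 5 adjusted over the list alone; adjusted p = 3.4e-05). Early genes of T cell receptor signalling fell in 17 of 33 cases and rose in 5 (20 and 5 adjusted over the list alone; adjusted p = 2.64e-06). Nr4a3 (-1.64 ± 0.14) and Egr3 (-1.04 ± 0.09) were among them. In the TGFβ response list 10 of 23 members fell and 2 rose (10 and 3 adjusted over the list alone; adjusted p = 0.000861). Its called members with the smallest p-values were Xcl1 and the gut-homing receptor Ccr9 (-3.42 ± 0.41). The cytotoxic (adjusted p = 0.293), T cell receptor (adjusted p = 0.0796) and TGFβ (adjusted p = 0.335) lists lost their calls with an estimated correlation.

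Metabolic genes changed in groups. Of 22 hypoxia-response genes 17 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 3.99e-11). Ndrg1 was at 154 against 39.5 CPM (log2 fold change 1.98 ± 0.22), and Ddit4, which encodes an inhibitor of the growth kinase mTORC1, rose by 1.57 ± 0.18. Of 24 cholesterol-synthesis genes 12 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 3.76e-05). Mvk (0.86 ± 0.14) and Fdft1 (0.85 ± 0.14) were among them. Glycolysis genes rose in 7 of 21 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00558). Aldoc rose (2.81 ± 0.47), while the lactate transporter gene Slc16a1 fell (-0.85 ± 0.14). Ribosome biogenesis and MYC target genes fell in 33 of 40 cases and rose in 0 (36 and 0 adjusted over the list alone; adjusted p = 1.41e-13). The nucleolar protein gene Ncl was at 1157 against 2307 CPM. Cell cycle genes (14 of 50 lower, 1 higher, the same adjusted over the list alone; adjusted p = 0.00267) fell, and so did unfolded protein response genes (7 of 24 lower, 0 higher, 9 and 0 adjusted over the list alone; adjusted p = 0.00294). With an estimated correlation none of these calls held, with adjusted p = 0.293 for hypoxia, 0.461 for cholesterol, ribosome and cell cycle genes, and 0.476 for glycolysis and the unfolded protein response.

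Lineage lists moved apart in the same comparison. The CD4 lineage list rose (10 of 16 members higher, 0 lower, the same adjusted over the list alone; camera adjusted p = 2.48e-05). Its called members included genes that regulatory T cells also express, such as Foxp3, Lrrc32 and Tnfrsf4. The CD8 lineage list fell (4 of 20 lower and 1 higher, 4 and 0 adjusted over the list alone; adjusted p = 0.0128). Mitochondrially encoded transcripts rose (5 of 13 higher, 0 lower, 6 and 0 adjusted over the list alone; adjusted p = 0.00586). Neat1, a nuclear non-coding RNA, was at 358 against 89.1 CPM. The largest rises were those of the transcription factor gene Lyl1 (ENSMUSG00000034041; 8.39 against 0.155 CPM, log2 fold change 5.75), Tph1 (4.68 ± 0.59) and the laminin-binding integrin gene Itga7 (8.37 against 0.586 CPM, 3.89 ± 0.44). They were followed by Slc26a10 (3.54 ± 0.42), Pygl (3.40 ± 0.32), Selenbp1 (3.22 ± 0.70), Col6a2 (3.14 ± 0.37) and Ier5l (3.05 ± 0.38). The inhibitory receptor gene Lag3 was at 135 against 27.4 CPM (2.32 ± 0.30, edgeR adjusted p = 0.000703). Calls of the CD4 lineage (adjusted p = 0.0618), CD8 lineage (adjusted p = 0.331) and mitochondrial (adjusted p = 0.461) lists were lost with an estimated correlation.

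Lists that were not called in this comparison were naive and memory genes (10 of 30 higher, 7 lower, camera adjusted p = 0.141) and inhibitory receptors (9 of 23 higher, 5 lower, adjusted p = 0.171). The test did not call oxidative phosphorylation (6 of 43 higher, 2 lower, adjusted p = 0.578), ATF4 targets (7 of 26 higher, 4 lower, adjusted p = 0.156) and p53 targets (3 of 23 higher, 7 lower, adjusted p = 0.361). Laminin receptors and adhesion genes (10 of 33 higher, 2 lower, adjusted p = 0.113) and actin genes (9 of 25 higher, 1 lower, adjusted p = 0.0526) were not called either. The same held for homing receptors (5 of 19 higher, 9 lower, adjusted p = 0.26), helper regulators (7 of 27 higher, 8 lower, adjusted p = 0.113) and IL-2 response genes (6 of 26 higher, 8 lower, adjusted p = 0.154). Adjusted over the list alone, the counts became 5 higher and 2 lower for oxidative phosphorylation, 9 and 4 for ATF4 targets, 3 and 8 for p53 targets, 10 and 2 for actin genes, 6 and 9 for homing receptors and 7 and 9 for IL-2 response genes, with no change for the others of these lists. Markers of other cells were not called for B cells (adjusted p = 0.649), myeloid cells (0.0873), natural killer cells (0.846) or stromal cells (0.284), nor were nuclear non-coding RNAs (0.109). Median and mean differed in sign for the naive, homing and helper lists, and the median of the natural killer list differed in sign from its test.

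Counts of changed genes leaned on single libraries. The 4320 became 2768, 2521 and 2590 without library 1, 2 or 3 of the group without laminin. They became 4820, 1752 and 1734 without library 1, 2 or 3 of the group labelled laminin. CPM did not overlap between the groups for 54.3% of genes, where chance gives 10%.

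The second comparison asked what anti-interferon-γ changed on laminin, as the labels have it. Of 37 interferon-γ response genes 23 were higher in the libraries labelled laminin plus anti-interferon-γ than in those labelled laminin alone, as were 6 of 31 type I and 6 of 26 cytotoxic genes, and Foxp3 was lower. All 13 lists called in this comparison lost their calls with an estimated correlation, these 3 at adjusted p = 0.0698, 0.497 and 0.315. Irf1 was at 209 against 82.1 CPM (log2 fold change 1.36 ± 0.11, edgeR adjusted p = 0.000145), and Foxp3 was at 279 ± 36.7 against 433 ± 24.7 CPM (SD, n = 3 each; -0.62 ± 0.11, adjusted p = 0.0155). Ifng itself did not pass the test, at 2.61 ± 0.779 against 2.55 ± 0.811 CPM (0.04 ± 0.30, adjusted p = 0.957). There were 386 changed genes (220 higher and 166 lower), 159 of them by at least 2-fold (78 higher and 81 lower).

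Of 37 interferon-γ response genes 23 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 2.24e-44). The median of the list was 0.91. Irf1 and Nlrc5, a regulator of MHC class I genes (1.10 ± 0.10), rose. So did Iigp1 (3.78 ± 0.41), Ly6a (3.54 ± 0.32) and Gbp6 (3.31 ± 0.34). The type I interferon list rose with 6 of 31 members higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 5.27e-09). Oas3 (1.38 ± 0.18) was among them. Against the mean of the 9 libraries the median of this list was 0.18 and 0.21 in replicates 2 and 3 of the anti-interferon-γ group, but -1.11 in replicate 1, below every library labelled laminin (-0.67, -1.02 and -0.82). Gzmb was at 1514 ± 84.9 against 447 ± 21.1 CPM (1.77 ± 0.18, adjusted p = 0.000772). Of 26 cytotoxic genes 6 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 1.25e-05). Helper regulators rose (6 of 27 higher, 3 lower, 12 and 3 adjusted over the list alone; adjusted p = 9.23e-07). Tbx21 was at 27.2 against 9.15 CPM (1.58 ± 0.13, adjusted p = 0.000145), and Il12rb2, which encodes a chain of the IL-12 receptor, at 121 against 15.9 CPM (2.94 ± 0.13, adjusted p = 1.78e-06). All 4 lists lost their calls with an estimated correlation (adjusted p = 0.0698 for interferon-γ, 0.497 for type I, 0.315 for cytotoxic and 0.0792 for helper genes).

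The regulatory T cell list fell (7 of 31 lower and 1 higher, 11 and 4 adjusted over the list alone; camera adjusted p = 0.00056). Nrp1, a receptor found on regulatory T cells, was at 2.00 ± 0.254 against 26.0 ± 2.33 CPM (log2 fold change -3.68 ± 0.29, edgeR adjusted p = 0.000145). The chemokine receptor gene Ccr4 changed by -1.46 ± 0.12. Entpd1, which encodes the ectonucleotidase CD39, rose against the list (0.88 ± 0.14). The CD4 lineage list fell (5 of 16 lower, 0 higher, 5 and 1 adjusted over the list alone; adjusted p = 0.000936). The CD8 lineage list rose (3 of 20 higher, 0 lower, 4 and 0 adjusted over the list alone; adjusted p = 0.00253), a call lost without replicate 1 of the anti-interferon-γ group (adjusted p = 0.0618). Il2ra (-0.09 ± 0.14, adjusted p = 0.769), Ctla4 (0.17 ± 0.16, adjusted p = 0.589), Ikzf2 (0.78 ± 0.34, adjusted p = 0.236), and Cd8a (0.06 ± 0.07) did not pass the test. The same held for Cd4 (-0.04 ± 1.06), Tgfb1 (-0.24 ± 0.13, adjusted p = 0.333), Itga6 (-0.26 ± 0.13, adjusted p = 0.308), Itgb1 (-0.02 ± 0.13) and Dag1 (0.15 ± 0.12). Foxp3 lost its call without library 2 (-0.58) or 3 (-0.62) of the laminin group or library 2 of the anti-interferon-γ group (-0.65). Calls of the regulatory T cell (adjusted p = 0.0698), CD4 lineage (adjusted p = 0.12) and CD8 lineage (adjusted p = 0.337) lists were lost with an estimated correlation.

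Further large rises were those of AC151990.1 (4.02 ± 0.52), Ly6c2 (2.22 ± 0.30), Tbkbp1 (1.96 ± 0.22) and the activating receptor gene Klrk1 (1.93 ± 0.30, a call lost without library 3 of the laminin group at 1.95). Steep falls were found for the imprinted non-coding RNA H19 (-3.40 ± 0.26), Igfbp7 (-2.87 ± 0.39), Tnfrsf25 (-2.83 ± 0.33), Col6a2 (-2.69 ± 0.36), Acsl6 (-2.38 ± 0.28), Adamtsl4 (-2.16 ± 0.27) and Pla2g4f (-2.11 ± 0.23). The interferon-γ receptor gene Ifngr2 changed by -1.31 ± 0.15, opposite to its rise of 1.65 ± 0.15 in the first comparison.

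Several lists were called in this comparison although 0 or 1 of their members passed. Oxidative phosphorylation genes were lower as a list (0 of 43 called, also 0 adjusted over the list alone; camera adjusted p = 9.23e-07). Mitochondrially encoded transcripts were lower (0 of 13 called, 5 lower adjusted over the list alone; adjusted p = 0.00247), and missed the threshold without library 2 of the laminin group (adjusted p = 0.0675). Ribosome biogenesis genes were lower (0 of 40 called, also 0 adjusted over the list alone; adjusted p = 0.000875). That call was lost without library 1 of the laminin group (adjusted p = 0.292), and the sign turned without replicate 1 of the anti-interferon-γ group (adjusted p = 0.982). Glycolysis (0 of 21 called, 1 higher adjusted over the list alone), hypoxia (0 of 22 called, also 0 adjusted over the list alone) and p53 genes (1 of 23 higher, 3 adjusted over the list alone) were higher, each at adjusted p = 0.0318. Glycolysis lost its call without library 1 of the laminin group (0.123) or library 1 (0.0618) or 3 (0.0774) of the anti-interferon-γ group. Hypoxia lost it without the same libraries (0.315, 0.114 and 0.0626), and p53 without replicate 1 of the anti-interferon-γ group (0.343). With an estimated correlation none of these calls held, with adjusted p = 0.697 for oxidative phosphorylation and p53, 0.696 for mitochondrial transcripts, and 0.738 for ribosome, glycolysis and hypoxia genes. Median and mean differed in sign for TGFβ response genes (2 of 23 higher, adjusted p = 0.627), naive and memory genes (2 of 30 higher, 2 lower, adjusted p = 0.865) and B cell markers (adjusted p = 0.867), which were not called.

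The 386 changed genes became 88 and 87 without library 2 or 3 of the laminin group, and 612 and 146 without library 1 or 2 of the anti-interferon-γ group. CPM did not overlap between these groups for 23.9% of genes, where chance gives 10%.

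The third comparison set the libraries labelled laminin plus anti-interferon-γ against those without laminin. Foxp3 did not differ by more than the spread between libraries (279 ± 36.7 against 294 ± 20.8 CPM, SD, n = 3 each; log2 fold change -0.06 ± 0.11, edgeR adjusted p = 0.695). Gzmb (0.07 ± 0.18, adjusted p = 0.793) and Tbx21 (-0.27 ± 0.12, adjusted p = 0.101) did not pass the test either. Tbx21 passed without library 3 of the anti-interferon-γ group (-0.39). Ifng fell (2.61 ± 0.779 against 44.4 ± 9.02 CPM, -4.07 ± 0.27, adjusted p = 2.38e-05). The cytokine and chemokine list (16 of 21 members) and the ribosome biogenesis list (39 of 40) fell, and the hypoxia (20 of 22), cholesterol (18 of 24) and glycolysis (11 of 21) lists rose. Only the cytokine and chemokine call held with an estimated correlation (adjusted p = 0.00249), against adjusted p = 0.462 for ribosome and cholesterol, 0.36 for hypoxia and 0.463 for glycolysis genes. The changed genes numbered 4584 (2406 higher and 2178 lower), 1248 of them by at least 2-fold (902 higher and 346 lower).

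Ctla4 rose (482 against 268 CPM, 0.86 ± 0.16, edgeR adjusted p = 0.00415). So did Lrrc32 (0.78 ± 0.08), Lag3 (185 against 27.4 CPM, 2.78 ± 0.30) and Prdm1, which encodes the terminal differentiation factor Blimp-1 (29.9 against 3.57 CPM, 3.09 ± 0.33). Irf1 was lower (-0.43 ± 0.11, adjusted p = 0.0138), a call lost without library 2 (-0.42) or 3 (-0.38) of the group without laminin. Il2ra was lower (-0.41 ± 0.14, adjusted p = 0.0464), a call lost without library 1 (-0.40), 2 (-0.43) or 3 (-0.39) of the group without laminin or replicate 1 of the anti-interferon-γ group (-0.24). Ikzf2 (0.35 ± 0.33), Cd8a (-0.05 ± 0.07), Cd4 (0.17 ± 1.05), Tgfb1 (0.03 ± 0.13), Itga6 (-0.09 ± 0.13), Itgb1 (-0.21 ± 0.13, adjusted p = 0.215) and Dag1 (0.05 ± 0.11) did not pass the test. Regulatory T cell genes as a list were not called (7 of 31 higher and 8 lower, adjusted p = 0.558, with a median and mean of opposite signs).

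Of 21 cytokine and chemokine genes 16 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 2.06e-23), and this call held with an estimated correlation (adjusted p = 0.00249). Ccl1 (-5.62 ± 0.37), Ccl3 (-3.84 ± 0.21), Ccl4 (-2.65 ± 0.15) and Xcl1 (-2.39 ± 0.15) fell. Other steep falls were those of Lad1 (-5.35 ± 0.75), Ccr9 (-4.99 ± 0.46), the co-stimulatory ligand gene Tnfsf4 (-3.26 ± 0.24), H19 (-3.07 ± 0.26) and the antiviral gene Mx2 (-2.97 ± 0.49). Early T cell receptor genes fell in 16 of 33 cases and rose in 3 (18 and 3 adjusted over the list alone; adjusted p = 3.43e-09). Egr3 (-1.83 ± 0.10) and Egr2 (-1.56 ± 0.17) were among them. Interferon-γ response genes fell in 17 of 37 cases and rose in 2 (the same adjusted over the list alone; adjusted p = 5e-05). Type I interferon genes fell in 23 of 31 cases and rose in 0 (24 and 0 adjusted over the list alone; adjusted p = 1.05e-12), Isg15 among them (-2.20 ± 0.38). Replicate 1 of the anti-interferon-γ group lay lower than its other replicates in both interferon lists. Against the mean of the 9 libraries the interferon-γ list was at -0.20, 0.32 and 0.33 in replicates 1 to 3 and at 0.43, 0.68 and 0.80 without laminin, and the type I list at -1.11, 0.18 and 0.21. TGFβ response genes fell in 7 of 23 cases and rose in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.00374). Calls of the T cell receptor (adjusted p = 0.0604), interferon-γ (adjusted p = 0.463), type I (adjusted p = 0.462) and TGFβ (adjusted p = 0.463) lists were lost with an estimated correlation.

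Ribosome biogenesis genes fell in 39 of 40 cases and rose in 0 (40 and 0 adjusted over the list alone; camera adjusted p = 3.62e-22). Ncl was at 1252 against 2307 CPM (-0.87 ± 0.13). The unfolded protein response fell in 14 of 24 cases and rose in 0 (17 and 0 adjusted over the list alone; adjusted p = 4.47e-05). Hypoxia-response genes rose in 20 of 22 cases and fell in 0 (21 and 0 adjusted over the list alone; adjusted p = 7.03e-16). Ndrg1 was at 204 against 39.5 CPM (2.39 ± 0.22). Cholesterol-synthesis genes rose in 18 of 24 and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 4.88e-08), Hmgcs1 among them (0.91 ± 0.14). Glycolysis genes rose in 11 of 21 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 2.33e-05). Aldoc was at 221 against 21.7 CPM, and the glucose transporter gene Slc2a3 rose by 1.69 ± 0.31. The rises of Tph1 (4.29 ± 0.59), Itga7 (4.02 ± 0.44), Pygl (3.93 ± 0.32) and Selenbp1 (3.79 ± 0.70) were again among the 8 largest, beside Dnm1 (4.96 ± 1.11) and Scrt1 (4.47 ± 0.67). None of these calls held with an estimated correlation (adjusted p = 0.462 for ribosome and cholesterol genes, 0.477 for the unfolded protein response, 0.36 for hypoxia and 0.463 for glycolysis).

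Weaker calls were those of cell cycle genes (12 of 50 lower, 2 higher, the same adjusted over the list alone; camera adjusted p = 0.0284) and oxidative phosphorylation (8 of 43 lower, 0 higher, 0 and 0 adjusted over the list alone; adjusted p = 0.0164). ATF4 targets (10 of 26 higher, 3 lower, 12 and 3 adjusted over the list alone; adjusted p = 0.0272) were higher, as were laminin receptors and adhesion genes (11 of 33 higher, 3 lower, 12 and 3 adjusted over the list alone; adjusted p = 0.0266). Without replicate 1 of the anti-interferon-γ group the cell cycle (0.0801), oxidative phosphorylation (0.12) and adhesion (0.12) calls were lost. Oxidative phosphorylation also missed the threshold without library 2 of the group without laminin (0.0735), and ATF4 targets without its library 3 (0.128) or library 2 (0.0509) or 3 (0.0944) of the anti-interferon-γ group. With an estimated correlation the values were adjusted p = 0.612 for the first 3 of these lists and adjusted p = 0.477 for the adhesion list. Among the genes of these lists, Pck2 (1.93 ± 0.28) and the collagen-binding integrin gene Itga2 (2.23 ± 0.24) rose. Median and mean differed in sign for cytotoxic genes (3 of 26 higher, 7 lower, adjusted p = 0.159), CD8 lineage genes (4 of 20 higher, 3 lower) and p53 targets (5 of 23 higher, 2 lower, the last 2 lists at adjusted p = 0.558), which were not called. The 4584 changed genes became 2990, 2497 and 3016 without library 1, 2 or 3 of the group without laminin, and CPM did not overlap for 50.6% of genes, where chance gives 10%.

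**Figure D3:**
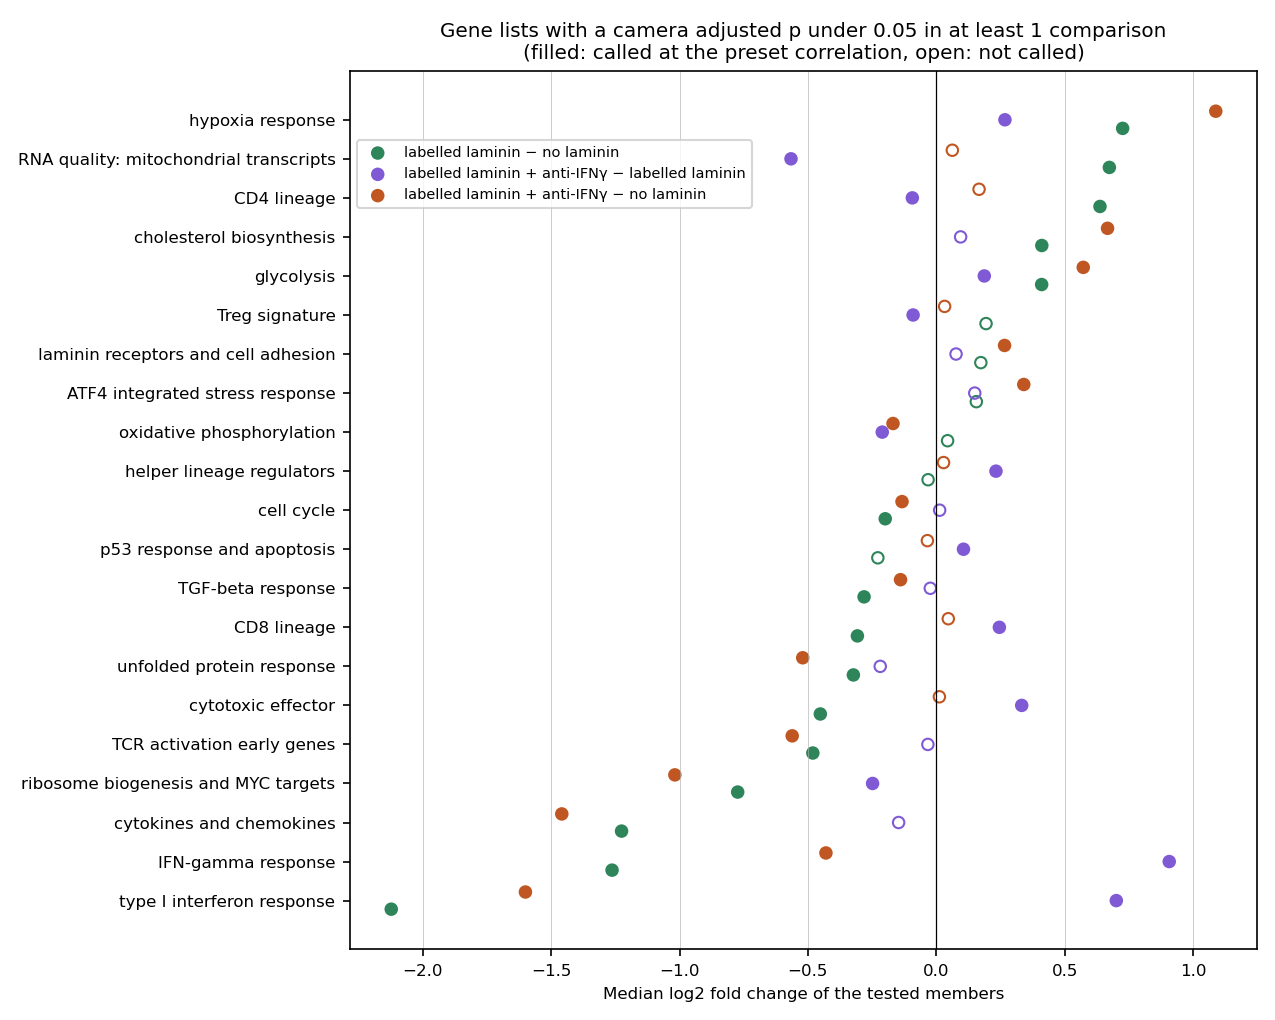
Median log2 fold change (x axis) of the tested members of each gene list (y axis) in the 3 comparisons among CD8 iTreg groups, 1 point per list and comparison, filled where camera called the list at the preset correlation. The interferon-γ list lies at -1.26 for labelled laminin against no laminin and at 0.91 between the 2 laminin groups, while the hypoxia list lies above 0 in all 3.

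The comparisons share libraries, so part of any relation between them arises by chance. Fold changes of both laminin groups against the group without laminin had a correlation across genes of 0.79, against 0.49 in simulated groups with no effect, and a covariance of 0.396 against 0.0376 simulated. Of 2227 genes that rose with labelled laminin, 1511 also rose with labelled laminin plus anti-interferon-γ (391 for independent lists), and of 2093 that fell 1291 also fell (332 for independent lists). Values for independent lists leave out the shared libraries. Of the 4320 genes called with labelled laminin, 95.5% had the same sign with labelled laminin plus anti-interferon-γ. In the simulated groups 79.6% of as many top genes did. Fold changes of the first 2 comparisons had a correlation of -0.31 against -0.52 simulated and a covariance of -0.0985 against -0.0405 simulated. Between the 2 laminin groups 65.6% of the 4320 genes had the opposite sign, against 80.7% of as many simulated top genes. The correlation and the share of opposite signs were thus weaker than simulated, while the covariance was stronger. Together they do not settle whether the second change undoes the first. Part of each relation may come from the shared libraries, which were too few to split.

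The fourth comparison asked how CD8 iTregs without laminin (3 libraries) differed from CD4 iTregs (1 library). CD8 iTregs had lower transcript levels of 22 of 33 regulatory T cell genes and 20 of 29 helper genes and higher levels of 31 of 50 cell cycle genes. The first 2 list calls held with an estimated correlation (adjusted p = 0.00363 and 0.0289) and the cell cycle call was lost (adjusted p = 0.264). Cd8a (log2 fold change 6.23 ± 0.17, edgeR adjusted p = 1.34e-09) was higher and Cd4 (ENSMUSG00000023274; 3.88 ± 3.76 against 553 CPM, -7.11 ± 1.12, adjusted p = 0.00142) lower. Foxp3 was at 294 ± 20.8 against 418 CPM (-0.51 ± 0.15, adjusted p = 0.024), a call that was lost without library 1 (-0.46) or 2 (-0.51) of the CD8 group. In this comparison 5250 of 15600 genes differed (2591 higher and 2659 lower in CD8 iTregs). Of these 2706 differed by at least 2-fold (1005 higher and 1701 lower). The share higher was 49.4%, and 41.5% with RLE scaling and 41.9% with no low-count filter.

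Of 33 regulatory T cell genes 22 were lower and 4 higher in CD8 iTregs (22 and 5 adjusted over the list alone; camera adjusted p = 1.21e-10). Ctla4 was at 268 against 1253 CPM (-2.23 ± 0.20, edgeR adjusted p = 1.32e-05), and Il10, the gene of an anti-inflammatory cytokine, at 1.74 against 123 CPM (-6.17 ± 0.26). Tnfrsf4 was lower (-3.29 ± 0.15) and Ikzf2 higher (49.5 against 5.75 CPM, 3.10 ± 0.59, adjusted p = 0.00264). Il2ra did not pass (-0.40 ± 0.20, adjusted p = 0.139). Helper regulators were lower in 20 of 29 cases and higher in 4 (22 and 5 adjusted over the list alone; adjusted p = 8.3e-09). Gata3, the gene of a type 2 helper regulator, was at 21.1 against 320 CPM (-3.92 ± 0.17), and Maf at 7.40 against 407 CPM. CD4 lineage genes were lower in 17 of 19 cases and higher in 1 (the same adjusted over the list alone; adjusted p = 2.49e-12). CD8 lineage genes were higher in 15 of 20 and lower in 3 (the same adjusted over the list alone; adjusted p = 2.4e-06), Cd8b1 (6.11 ± 0.26) and Xcl1 (256 against 0.733 CPM) among them. With an estimated correlation the regulatory T cell (adjusted p = 0.00363), helper (adjusted p = 0.0289) and CD4 lineage (adjusted p = 0.00363) calls held, and the CD8 lineage call was lost (adjusted p = 0.109).

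Cytotoxic genes went both ways (9 of 28 higher, 14 lower, 9 and 15 adjusted over the list alone; camera adjusted p = 0.0446). That call was lost with RLE scaling (0.056) and without library 2 (0.0572) or 3 (0.0783) of the CD8 group. Gzma was at 32.9 against 2389 CPM and Gzmb at 1464 ± 442 against 2934 CPM (edgeR adjusted p = 0.00822). The receptor gene Klrd1 was higher (5.70 ± 0.47). Ifng was at 44.4 ± 9.02 against 16.8 CPM (1.40 ± 0.34, adjusted p = 0.00935), Irf1 at 1.07 ± 0.17 (adjusted p = 0.000647) and Tbx21 at -0.45 ± 0.17 (adjusted p = 0.0617). Tbx21 passed with RLE scaling (-0.52). Interferon-γ response genes were higher in 19 of 37 cases and lower in 6 (21 and 7 adjusted over the list alone; adjusted p = 0.00645). Among laminin receptors, Itga6 was higher (226 ± 37.1 against 52.9 CPM, 2.09 ± 0.21, adjusted p = 2.98e-05), as were Itgb1 (0.69 ± 0.19, adjusted p = 0.0156) and Dag1 (0.61 ± 0.17, adjusted p = 0.0195). Itgb3 was lower (11.8 against 592 CPM), and so was the adhesion list (15 of 35 lower, 7 higher, 16 and 8 adjusted over the list alone; adjusted p = 0.0162). With an estimated correlation the cytotoxic, interferon-γ (both adjusted p = 0.494) and adhesion (adjusted p = 0.338) lists lost their calls. Tgfb1 was lower (-0.67 ± 0.18, adjusted p = 0.0129).

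Cell cycle genes were higher in 31 of 50 cases and lower in 0 (39 and 1 adjusted over the list alone; camera adjusted p = 4.28e-09), the checkpoint kinase gene Bub1 by 1.10 ± 0.13. ATF4 targets, genes of the amino acid stress response, were lower in 22 of 27 cases and higher in 0 (the same adjusted over the list alone; adjusted p = 5.26e-11), among them Ddit3 (-3.56 ± 0.27). Ribosome biogenesis genes were higher in 18 of 40 cases (25 adjusted over the list alone; adjusted p = 2.4e-06). Inhibitory receptors were lower in 13 of 25 and higher in 8 (15 and 9 adjusted over the list alone; adjusted p = 0.000856). Lag3 was at 27.4 against 559 CPM. B cell markers were higher (5 of 6 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.00656), with the immunoglobulin gene Ighm at 966 against 225 CPM. Stromal markers were lower (5 of 10 lower, 1 higher, the same adjusted over the list alone; adjusted p = 0.0231). None of these calls held with an estimated correlation, with adjusted p = 0.264 for cell cycle genes and stromal markers, 0.26 for ATF4 targets, 0.494 for ribosome genes, 0.338 for inhibitory receptors and 0.123 for B cell markers. Genes with 0 counts in all 3 CD8 libraries were at least 527-fold lower for Htr1b (ENSMUSG00000049511), 402-fold for Ermn and 232-fold for the cytokine gene Il21, and Il5 was at least 157-fold lower. Myrip was higher in CD8 iTregs with a ratio of 114 (95% counting interval 31.4 to 937).

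Further lists were called between CD8 and CD4 iTregs. Naive and memory genes were higher in 16 of 30 cases and lower in 7 (16 and 8 adjusted over the list alone; camera adjusted p = 0.0162), with the chromatin organiser gene Satb1 going the other way (133 against 936 CPM, log2 fold change -2.81 ± 0.19). Cytokine genes were lower in 13 of 29 cases and higher in 8 (15 and 10 adjusted over the list alone; adjusted p = 0.018), with Il24 at 3.61 against 170 CPM. Early T cell receptor genes were lower in 16 of 35 and higher in 10 (the same adjusted over the list alone; adjusted p = 0.018), with the AP-1 gene Fosl2 lower (-5.10 ± 0.21). Homing receptors were lower in 10 of 20 and higher in 4 (11 and 5 adjusted over the list alone; adjusted p = 0.0183), with Ccr8 lower (-4.06 ± 0.29). Cholesterol genes were lower in 11 of 25 and higher in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.00848), Fdft1 among them (-1.12 ± 0.18). Oxidative phosphorylation genes were higher in 8 of 43 (4 adjusted over the list alone; adjusted p = 0.0107) and mitochondrially encoded transcripts in 4 of 14 (the same adjusted over the list alone; adjusted p = 0.0119), with mt-Nd2 at 602 against 229 CPM. All of these calls were lost with an estimated correlation, with adjusted p = 0.264 for cytokine, T cell receptor and homing genes, 0.494 for naive, cholesterol and mitochondrial genes and 0.669 for oxidative phosphorylation. Glycolysis (adjusted p = 0.907), unfolded protein response (adjusted p = 0.688) and myeloid genes (adjusted p = 0.66) were not called, and their medians differed in sign from the test.

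The fifth comparison set CD8 iTregs without laminin (3 libraries) against naive CD8 T cells (1 library). The lists of regulatory T cell, cell cycle, oxidative phosphorylation and glycolysis genes were higher in iTregs, and the list of naive T cell genes was lower. Only the regulatory T cell call held with an estimated correlation (adjusted p = 0.00438), against adjusted p = 0.0881 for cell cycle, 0.156 for naive and 0.447 for oxidative phosphorylation and glycolysis genes. Foxp3 was at 294 ± 20.8 against 0.557 CPM (log2 fold change 9.03 ± 0.31, edgeR adjusted p = 1.18e-09), and Il2ra at 2881 ± 70.8 against 0.390 CPM (12.83 ± 0.44, adjusted p = 1.21e-09). The iTregs were sorted for Foxp3, so a higher Foxp3 level was set by the sort. Ctla4 was at 268 ± 61.5 against 1.00 CPM (8.05 ± 0.40, adjusted p = 1.93e-08). In all, 9256 of 15600 genes differed (5106 higher and 4150 lower), 6278 of them by at least 2-fold (3637 higher and 2641 lower). The median log2 fold change of all genes was 0.13, and 0.06 with RLE scaling, so smaller changes are relative to that shift. The naive library also had the highest share of reads outside genes (13.0% no feature against 6.21% to 9.59% in the 9 replicated libraries). Near-identical gene copies differed between this library and the rest, as described under other observations. Part of the 9256 may thus come from how reads were assigned among copies, which stays open.

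Of 33 regulatory T cell genes 31 were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 1.69e-12), and this call held with an estimated correlation (adjusted p = 0.00438). Lrrc32 had 0 counts in the naive library and was at least 892-fold higher. All 50 cell cycle genes were higher (50 and 0 adjusted over the list alone; adjusted p = 1.95e-29). Among genes of cell division Bub1 was at least 719-fold higher, Nuf2 at least 507-fold higher and the cyclin gene Ccna2 at 9.28 ± 0.23. Naive and memory genes were lower in 26 of 30 cases and higher in 2 (the same adjusted over the list alone; adjusted p = 3.05e-11). They included Als2cl (77.9 against 1184 CPM, -3.93 ± 0.18), Dapl1 (-4.75 ± 0.23) and Evl (-2.90 ± 0.15). Ifng (0 counts in the naive library) was at least 266-fold higher (edgeR adjusted p = 6.19e-07). Gzmb was at 1464 ± 442 against 0.390 CPM (11.85 ± 0.54, adjusted p = 1.05e-08) and Tbx21 at 33.2 against 5.63 CPM (2.56 ± 0.22). Cytotoxic genes were higher in 18 of 28 cases and lower in 4 (the same adjusted over the list alone; adjusted p = 0.0141), but the pore-forming protein gene Prf1 was lower (-1.69 ± 0.16). Cytokine genes were higher in 17 of 29 and lower in 2 (the same adjusted over the list alone; adjusted p = 0.000255). The cell cycle (adjusted p = 0.0881), naive (adjusted p = 0.156), cytotoxic (adjusted p = 0.447) and cytokine (adjusted p = 0.156) lists lost their calls with an estimated correlation.

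Oxidative phosphorylation genes were higher in 41 of 43 cases and lower in 0 (42 and 0 adjusted over the list alone; camera adjusted p = 1.34e-10), among them Cox5a (2.28 ± 0.18). Cholesterol-synthesis genes were higher in 21 of 25 (the same adjusted over the list alone; adjusted p = 4.7e-07), such as Sqle (3.10 ± 0.19). Glycolysis genes were higher in 18 of 21 cases and lower in 1 (the same adjusted over the list alone; adjusted p = 1.16e-05), such as the hexokinase gene Hk2 (5.52 ± 0.33). ATF4 targets were higher in 21 of 27 and lower in 2 (the same adjusted over the list alone; adjusted p = 0.000158), with the asparagine synthetase gene Asns at least 471-fold higher. IL-2 response genes were higher in 19 of 26 and lower in 3 (the same adjusted over the list alone; adjusted p = 5.13e-06), among them Cish (4.68 ± 0.16), the gene of a cytokine signal inhibitor. Ribosome biogenesis genes were higher in 26 of 40 (28 adjusted over the list alone; adjusted p = 0.000218). Other lists that were higher were the unfolded protein response (17 of 24 higher, 2 lower, the same adjusted over the list alone; adjusted p = 0.00578) and early T cell receptor genes (19 of 35 higher, 8 lower, the same adjusted over the list alone; adjusted p = 0.00752). Interferon-γ response genes were higher in 20 of 37 cases and lower in 5 (the same adjusted over the list alone; adjusted p = 0.0255). Inhibitory receptors were higher in 16 of 25 cases and lower in 5 and hypoxia genes in 14 of 23 and lower in 2 (both the same adjusted over the list alone, and both at adjusted p = 0.0105), with Entpd1 at 44.0 against 0.223 CPM. CD4 lineage genes were higher in 9 of 19 and lower in 5 (10 and 5 adjusted over the list alone; adjusted p = 0.0403). None of these calls held with an estimated correlation. The values were adjusted p = 0.447 for oxidative phosphorylation, cholesterol, glycolysis, ATF4 and inhibitory receptor genes, 0.156 for IL-2 response genes and 0.245 for CD4 lineage genes. They were adjusted p = 0.651 for ribosome, hypoxia and interferon-γ genes, 0.63 for the unfolded protein response and 0.309 for T cell receptor genes.

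Tgfb1 (1.53 ± 0.20, edgeR adjusted p = 5.15e-05), Ikzf2 (2.14 ± 0.54, adjusted p = 0.00526), Itgb1 (1.79 ± 0.20, adjusted p = 1.58e-05) and Cd8a (0.36 ± 0.11, adjusted p = 0.0165) were higher in iTregs. Irf1 (-0.17 ± 0.15, adjusted p = 0.373) and Dag1 (-0.22 ± 0.16, adjusted p = 0.274) did not pass, nor did Cd4 (3.88 ± 3.76 CPM against 0 counts, adjusted p = 0.147). Itga6 (0.48 ± 0.19, adjusted p = 0.0476) lost its call without library 3 of the iTreg group (0.33) and with RLE scaling (0.41). The adhesion list was not called (10 of 35 higher, 12 lower, camera adjusted p = 0.627), nor were homing receptors (8 of 20 higher, 7 lower, adjusted p = 0.994), and in both lists median and mean differed in sign. Itga4, an integrin chain used in homing, was lower (38.8 against 685 CPM, -4.14 ± 0.25). Other genes with 0 counts in the naive library were Igha (ENSMUSG00000095079), at least 2047-fold higher, the fatty acid desaturase gene Scd1, at least 1305-fold, Emilin2, at least 587-fold, and Emp1, at least 543-fold. Trnp1 had 0 counts in iTregs and was at least 758-fold lower, Pcsk1 was at least 244-fold lower, and the amino acid transporter gene Slc6a19 was at 0.230 against 170 CPM (-9.47 ± 0.66). Trim12a was at 0.0437 against 173 CPM, but its reads may be shared with related Trim genes.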

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

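The test of the exchanged labels was written before its result was seen, and the tests of single libraries and of the library splits were chosen after seeing the results. Many genes and lists differed between the 2 laminin groups by a test of the difference itself. From these the interferon-γ response list and Foxp3 were chosen for a closer look, so the test alone did not single them out.

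The interferon-γ response list was called between the 2 laminin groups by camera at the preset correlation, a call lost with an estimated correlation. The median log2 fold change of its members was 0.91, higher in the libraries labelled with the antibody against interferon-γ. An exchange of the 2 labels, which is what the names of the deposited tables have, would give this direction (0.91, prediction written before). Against a single unusual library stands that the median stayed at 0.877 or more whichever library was left out. Ifng itself was at 2.55 and 2.61 CPM in the 2 groups, so its own transcript does not tell them apart. A real rise of the response under the antibody or another difference between the 2 groups remains open, since the counts alone cannot show which label is right or what made the groups differ.

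Foxp3 was the other result chosen. It was 433 CPM in the libraries labelled laminin, 279 CPM in those labelled laminin plus anti-interferon-γ and 294 CPM without laminin. The log2 fold change between the 2 laminin groups was -0.62, and that call was lost without some single libraries, as given above. Whichever label is right, one laminin group had more Foxp3 transcript than the group without laminin and the other did not differ from it by the test. If the labels are exchanged (0.91 for the response list), the group with more Foxp3 would be the one that received the antibody.

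Of the 10 splits of 6 libraries into 3 and 3, which are too few for a share under 0.05, 1 split (the real one) gave at least as many genes in each comparison among CD8 iTreg groups. The real values were 4320, 386 and 4584 genes for laminin against none, anti-interferon-γ against laminin and anti-interferon-γ against none, and the highest other splits gave 0, 333 and 0 genes. Every other split mixed libraries of both groups, so the difference between the groups entered its spread. Low counts in those splits were thus likely in advance and say little about chance. The split with 333 genes exchanged replicate 1 of the 2 laminin groups and shared 0 genes with the 386.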

How the results depend on the processing

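The settings were listed before the data were examined, except the fits without replicate 1 of the anti-interferon-γ group where it is not compared and without genes that share sequence, chosen after seeing the results; the cause of a difference was not tested unless the setting itself shows it. Laminin against none (4320 genes) ranged from 1734 to 6141 with 1 library left out and gave 1063 with a fold of at least 2. Anti-interferon-γ against laminin (386) gave 933 with DESeq2, 152 with only the 6 libraries compared, 181 with the replicate number as a block, 159 with a fold of at least 2, and 87 to 612 with 1 library left out. Replicate numbers did not pair the libraries (same-number correlations -0.388 to 0.151), so the block uses up degrees of freedom. Across numbers, deviations from the group mean of laminin library 1 went with those of anti-interferon-γ libraries 2 and 3 (0.289 and 0.298). Those of anti-interferon-γ replicate 1 went with those of laminin libraries 2 and 3 (0.247 and 0.261). Deviations within a group sum to 0, so the -0.388 between replicate 1 of the 2 laminin groups itself pushes these values above 0. They and the split that called 333 genes restate 1 pattern and are not separate evidence that libraries pair. No fit took this pattern into account. Anti-interferon-γ against none (4584) ranged from 2497 to 4786 with 1 library left out and gave 1248 with a fold of at least 2. CD8 against CD4 iTregs (5250) gave 2706 and iTregs against naive cells (9256 of 15600 genes tested) gave 6278 with a fold of at least 2. Without genes that share sequence, 8073 of 13415 genes tested were called. The lower count goes with fewer genes tested and does not show how many calls came from shared sequence. With an estimated correlation 1 of 15, 0 of 13, 1 of 14, 3 of 20 and 1 of 17 lists stayed called in the order above. With fry, which does not compare a list with the other genes, 13 of 15, 4 of 13, 11 of 14, 16 of 20 and 17 of 17 stayed called. The ribosome list between the laminin groups ranged from adjusted p = 2.09e-07 to 0.982 with 1 library left out, and its sign reversed without replicate 1 of the anti-interferon-γ group (0.982). The correlation of fold changes of the first 2 comparisons moved from -0.31 to -0.23 in genes of at least 5 CPM. Of named-gene settings, 1062 of 1134, 672 of 783, 1074 of 1124, 643 of 664 and 627 of 635 kept the call or its absence, and 0 changed sign with a call.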

Other observations

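The tests of gene families with shared sequence, of library bias and of cells of another type were written before their results were seen, and those of part of the families and of mixed cells of 2 groups were chosen after seeing the results. In the libraries labelled laminin plus anti-interferon-γ the imprinted non-coding RNA H19 fell both against the laminin libraries (log2 fold change -3.40 ± 0.26) and against those without laminin (-3.07 ± 0.26).

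Replicate 1 of the laminin plus anti-interferon-γ group stood apart from replicates 2 and 3, at a root mean square log2 distance of 0.596 against at most 0.426 for any other library. GC content and transcript length are unlikely to explain it, as the distance stayed 0.589 after correction for both. Cells of another replicated group, in any share, are argued against as the whole cause: the nearest mixture of replicates 2 and 3 with such a group or 1 of its libraries (laminin library 3, share 30%) left a distance of 0.574, against at most 0.427 for any other library from the rest of its group. The bound written before (a ratio of distances below 1, here 0.922) was too weak, since a library with a small share of such cells would meet it too. Cells of another type stay open, with a highest list median (0.917, 5 stromal genes) between the bounds written before, and so does a difference in the culture or the sort, with type I interferon (-1.25), ribosome (-0.83) and mitochondrial (-0.58) genes lower than in replicates 2 and 3.

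Near-identical gene copies differed between the naive library and the rest, with Rps3a1 at 2426 against 600 CPM, Rps3a3 at 9.36 against 578 CPM and Rpl29 at 438 against 3.00 CPM. A different assignment of reads among copies stays open: the median spread of differences within families was 0.323, above the 0.146 of the CD4 library but below 0.687, the median absolute difference of family sums. The bound written before counted a value below the family sums against this explanation, but those sums also carry the difference between naive cells and iTregs, so it was too strict. The total of processed pseudogenes was lowest in the naive library, at 8923 against 12583 to 15742 CPM in the 10 others. The 445 that share at least 50% of their sequence had a median log2 difference of -0.425. The 53 that share little sequence were higher by 0.376 (interquartile range over the square root of their number 0.280). Less RNA of the class whatever its sequence is thus unlikely. For part of the families a different assignment of reads is open as well. Members parted by over 2 log2 units in 15.7% of families, against 0.437% in the CD4 library, but naive cells differed more in all genes. Read-level files, not analysed here, would be needed to settle which copies the reads came from.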
